A study of Rattus norvegicus with 16 samples.

How the data were processed

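The series holds 16 two-channel scans of spotted oligonucleotide arrays of rat liver RNA, with 4 arrays for each of 4 groups. Per the labels, the test RNA was labelled with Cy5 and the RNA of hypothyroid, orchidectomized rats (TXOX) with Cy3, and no array had the dyes swapped. Spot intensity values, with foreground and local background in each channel, are as scanned and not normalized, per the file headers. The percent of a spot's pixels above background plus 2 SD is likewise as scanned, per the file headers. The score that marks spot quality is the image analysis code of each spot, per the file headers. The submitters also deposited a table of log2 values, with no statement of how it was made. On the INTACT, TXOXGH and TXOXTP arrays it followed the log2 ratio of median foregrounds, Cy5 over Cy3, more closely without background subtraction than with it. On the TXOXTPGH arrays it followed the background-subtracted ratio more closely (r of 0.88, 0.85, 0.84 and 0.52, against 0.81, 0.73, 0.74 and 0.19).

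Mean foreground and median background intensities were read with limma 3.58.1 in R 4.3.3, and the background was corrected by normexp with an offset of 50. Each array was normalized by global loess, with control and bad spots at weight 0 and no scaling between arrays. Spots scored -100 were treated as missing and spots scored -50 (not found) were kept. Spots of 1 probe were averaged, which concerned 12 probes with 12 spots each. A probe was tested if every group had at least 3 values and if it was above background in either channel on at least 4 of the 16 arrays, where above background means at least 50% of pixels. This left 14170 probes. No sequencing depth applies, and the number of arrays limits the precision. The standard deviation between repeat spots of a probe within an array was 0.203 to 0.458 on the log2 scale. That between arrays of a group was 0.332 for INTACT, 0.284 for TXOXGH, 0.395 for TXOXTP and 0.358 for TXOXTPGH. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

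All 16 arrays entered 1 limma fit with a mean per group (12 residual and 7.27 prior degrees of freedom), and 10 comparisons were tested on both sides, with Benjamini-Hochberg adjustment over the tested probes at 0.05. Groups, tests, the rule for named probes and most alternatives were fixed before the data were examined; those added later are named as such. Comparisons against TXOX test a group's log2 ratios against 0. Per the file headers, arrays of the same number share a TXOX rat, which pairs them, while the 4 arrays of a group use 4 different TXOX rats, so the spread of TXOX rats is within each test. Same-numbered arrays of different groups deviated together with a mean r of 0.045 across probes (-0.20 to 0.31, 6 of 24 pairs above 0.1), differently numbered ones with -0.015 (-0.35 to 0.37), and 6 of 16 arrays correlated best with their own number. The fit with the replicate number as a block moved no count by over 1.5 times. Each group lies in 1 of the 2 batches that the Alien control spots mark, so the batch could not be fitted beside the group across batches.

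The fixed rule named probes by gene, and the files do not pair the probe IDs with gene names. The rat reference gene table of assembly GRCr8 matched 0 of the probe IDs. The 27 gene lists and the gene panel fixed beforehand were therefore not analysed here, nor the tests of lists with preset or estimated correlation. In their place the text names the 2 probes with the largest rise and the 2 with the largest fall in INTACT against TXOX among the called probes that changed in the same direction on all arrays (1960 of 2046). These 4 probes are followed through all comparisons. A fold against a channel that was above background on no array of a group is given as a lower bound, from normalized log2 values per channel with the dim signal at the lowest value above background or its own, whichever is higher, and is open to dye bias.

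Agreement with INTACT was described by correlations, covariances and slopes across probes. For slopes, the arrays were halved in 6 ways so that INTACT and the treated group had different TXOX rats on the 2 sides, and noise in INTACT was removed with the covariance between its own arrays. Unchanged groups sharing TXOX rats were simulated 100 times. Distances to INTACT used covariances between different arrays, which noise does not raise. The steps were tested on simulated data: with 14170 probes and 200 changed, INTACT against TXOX recovered 51 of 100 changes of 1.5-fold and 93 of 100 of 2-fold. Changes were added in full to normalized ratios, so a loss of signal in the background is not simulated. A true slope of 0.4 was recovered as 0.39 for TXOXGH and as 0.40 for TXOXTPGH without a dye bias. With a simulated fixed dye bias of SD 0.18 on the log2 scale, an assumed size, it came out as 0.52 in both, and a true slope of 0 in TXOXTP came out as 0.20. That size was set in proportion to the simulated INTACT changes (SD 0.36) and not estimated, so these biased slopes follow from the setting. With TXOXTP subtracted, the same biased data gave 0.39 and 0.40. A subtracted group stands on both sides of such a slope, so the slope that its own reproducible ratios alone would give was computed beside it as the no-change value. Calls shared with INTACT were counted in 25 simulations of unchanged groups and in the 6 halvings.

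The submitters' table lists 2902, 1512, 922 and 2155 probes for INTACT, TXOXGH, TXOXTP and TXOXTPGH, each on all 4 arrays of a group or on none, so it is a chosen list and a test on it is not independent evidence. The medians of its columns were 0.19, 0.30, 0.27 and 0.15 for INTACT replicates 1 to 4, and 0.21, 0.31, 0.32 and 0.34 for TXOXGH. They were 0.02, 0.38, 0.19 and 0.24 for TXOXTP, and -0.04, -0.08, -0.04 and -0.03 for TXOXTPGH. Against the scanner values, the direction (positive where Cy5 is brighter) and the log2 scale held on the INTACT arrays (r of 0.93 to 0.99), while the scale of the TXOXTPGH columns stays unknown. The centring of all columns stays unknown. Among its listed probes tested here, 99.5%, 96.8%, 97.0% and 96.1% had the same sign here.

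Alternatives concerned the background correction, the loess, scaling between arrays, the filter on dim probes, not-found spots, the foreground statistic, the replicate block, the arrays in the fit, each array left out, a 1.5-fold minimum, the submitters' values and the variance prior. Array weights, a filter per group, the median of pixels together with no background correction, probes of the highest mean intensity, and the omission of TXOXTP replicates 1 and 2 and TXOXTPGH replicate 4 were added after the data were seen. A scan day was not used as a block, since the file headers give none.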

Results

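Liver RNA of male Sprague Dawley rats was measured on 16 arrays, each carrying 26962 distinct oligonucleotide probes. Hypothyroid and orchidectomized rats (TXOX) received methimazole, a drug that blocks thyroid hormone synthesis, at 0.05% in the drinking water for 5 weeks and lost their testes after 2 weeks of it. The test RNA, labelled with Cy5, came from 4 groups of 4 rats: euthyroid rats with testes (INTACT), TXOX rats given growth hormone (TXOXGH), TXOX rats given testosterone propionate (TXOXTP), and TXOX rats given both (TXOXTPGH). Each array set 1 test rat against 1 of 4 TXOX rats in Cy3, and arrays of the same replicate number shared the TXOX rat. Growth hormone was given at 0.3 mg per kg per day in 2 injections for 7 days, and testosterone propionate at 50 µg per kg on 5 days per week, per the labels for 20 days before growth hormone and from 4 days after the loss of the testes. These times conflict, since the other times in the labels leave 17 days from the start of testosterone propionate to the end, and 20 and 7 days need 27. A positive log2 ratio means more RNA in the test rat than in the TXOX rat. The files do not pair probe IDs with gene names, so probes are given by ID, and the fixed gene lists were not tested.

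The arrays differed in signal by group. Between 26.9% and 60.7% of probe spots were above background in Cy5 on the INTACT and TXOXGH arrays, against 5.4% to 21.6% on the TXOXTP and TXOXTPGH arrays. The median Cy5 background was 633 to 713 intensity units on the TXOXTP arrays, 179 to 399 on the TXOXTPGH arrays, 132 to 192 on the TXOXGH arrays and 99 to 160 on the INTACT arrays. In Cy3 it was 585 to 1143 on the TXOXTP arrays and 38 to 177 on the TXOXTPGH arrays. Alien control spots were above background in Cy5 at 55.5% to 82.7% on the INTACT and TXOXGH arrays and at 1.8% to 7.3% on the others. This parts the arrays into 2 sets that each hold 2 whole groups, here called batches, although TXOXTP and TXOXTPGH differ in background. No label or file header states a batch. Empty spots were also less often above background in Cy5 on the TXOXTP and TXOXTPGH arrays, so the batches are inferred from signal alone. TXOXGH against INTACT and TXOXTPGH against TXOXTP are comparisons within a batch so marked. The other comparisons between test groups cross the batches, and there the batch and the group cannot be told apart by a fit. Nor can the difference in background between TXOXTP and TXOXTPGH arrays be told apart from the group. Replicate arrays of INTACT, TXOXGH and TXOXTPGH had a mean correlation of log2 ratios across probes of 0.55, 0.51 and 0.45, and those of TXOXTP 0.15. Probes are not independent replicates.

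**Figure D1:**
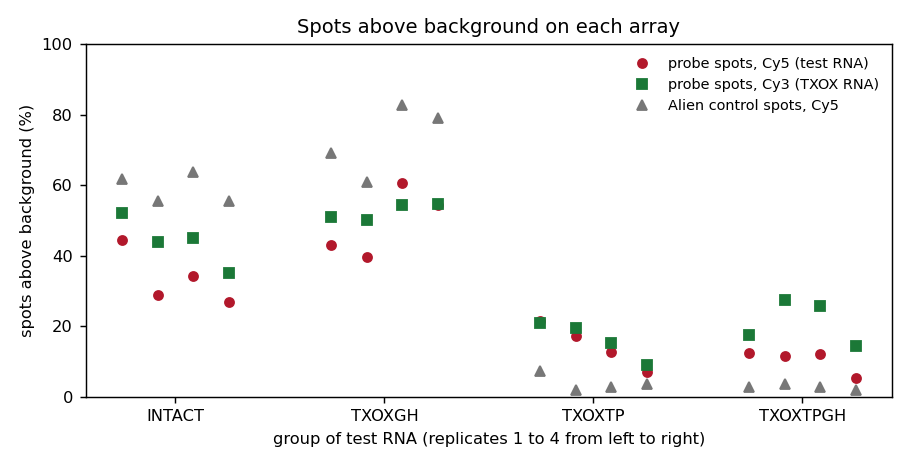
Percent of spots above background on each of the 16 arrays, by group, with 1 point per array for probe spots in Cy5 (test RNA), probe spots in Cy3 (TXOX RNA) and Alien control spots in Cy5. The TXOXTP and TXOXTPGH arrays lie below the INTACT and TXOXGH arrays in all 3 measures, with Alien spots at 1.8% to 7.3% against 55.5% to 82.7%.

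INTACT against TXOX asks what the loss of thyroid hormone and testes together changed in the liver. Of 14170 probes tested, 1006 were higher and 1040 lower in INTACT liver, with a median size of 0.58 on the log2 scale, and 156 of the higher and 86 of the lower ones differed by 2-fold or more. The largest rise was at probe Rn30016143, with a mean log2 ratio of 6.55 (SD 0.92, n = 4, limma adjusted p = 7.8e-07). Next was Rn30008202 at 6.04 (SD 0.60, n = 4, limma adjusted p = 1.2e-06), whose TXOX signal was above background on 1 of the 4 INTACT arrays. The largest falls were at R000733_01, at -2.86 (SD 0.53, n = 4, limma adjusted p = 2.7e-08), and at Rn30012216, at -2.84 (SD 0.19, n = 4, limma adjusted p = 1.3e-11). Both lower probes were above background in INTACT RNA on 1 of 4 arrays and in TXOX RNA on all 4. Each of the 4 probes changed in the same direction on all 4 INTACT arrays, and over the alternatives Rn30008202 ranged from 2.62 to 6.30 and Rn30012216 from -2.91 to -1.82. The count of 2046 became 1238 without INTACT replicate 2 and 913 without INTACT replicate 3, and 3104 with no background correction. With median centring in place of loess, 665 probes were higher and 1306 lower, and with no dye swap in the series a fixed dye bias stays in every comparison against TXOX.

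TXOXGH against TXOX asks what growth hormone alone changed in these rats. Growth hormone raised 513 probes and lowered 389, with a median size of 0.64 on the log2 scale. It moved all 4 probes named above in the INTACT direction. Rn30016143 stood at 5.40 (SD 1.97, n = 4, limma adjusted p = 2.7e-05) and Rn30008202 at 5.03 (SD 1.68, n = 4, limma adjusted p = 3.2e-05), while R000733_01 stood at -1.45 (SD 0.53, n = 4, limma adjusted p = 0.00019) and Rn30012216 at -1.70 (SD 0.26, n = 4, limma adjusted p = 5.9e-08). Over the alternatives Rn30008202 ranged from 1.74 to 5.63 and Rn30012216 from -1.82 to -1.13. TXOX signal at Rn30016143 and Rn30008202 was above background on 2 and 1 of the 4 TXOXGH arrays. Of the probes higher in INTACT, 232 of 1006 were also raised by growth hormone, and of the lower ones 178 of 1040 were also lowered, where independent lists would share 36.4 and 28.6. Simulated unchanged groups on shared TXOX rats shared 0, but had a mean of 0.04 to 0.07 calls each, so this value tests nothing about the shared rats. With different TXOX rats on the 2 sides, 24 to 42 higher and 10 to 31 lower probes were shared over 6 halvings, against a mean of 1.29 and 0.888 for independent lists. Independent lists do not allow for a fixed dye bias, which raises shared calls, so the excess does not measure a shared effect. Another 11 probes were called in opposite directions. The count of 902 became 372, 478 and 358 without TXOXGH replicates 2, 3 and 4, and 1485 when the TXOXGH arrays were fitted alone. It was 587 with print-tip loess, and median centring gave 524 higher and 239 lower.

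TXOXTP against TXOX asks what testosterone propionate alone changed. Here 14 probes passed the test, 7 higher and 7 lower, and 2009 had an unadjusted p under 0.05. Rn30016143 was higher at 4.22 (SD 1.83, n = 3, limma adjusted p = 0.014), with TXOX signal not above background on any TXOXTP array, so that the measured means give at least a 12.6-fold rise. The other 3 named probes did not pass, although all 3 did with the submitters' values, a chosen list (1.57 for Rn30008202, -0.48 for R000733_01 and -0.30 for Rn30012216), and R000733_01 also with no background correction and the median of pixels (-0.60). Rn30008202 had a measured mean of 2.16 (SD 2.10, limma adjusted p = 0.13) with TXOX signal above background on no TXOXTP array; the measured means give a ratio of at least 4.36-fold, which was not told from no change. R000733_01 stood at -0.60 (SD 0.38, limma adjusted p = 0.20) and Rn30012216 at -0.32 (SD 0.23, limma adjusted p = 0.25). In simulated data of this comparison with 14170 probes and 200 changed, 55 of 100 changes of 1.5-fold and 88 of 100 of 2-fold were recovered, with 26 of 169 calls wrong. The changes were added in full to normalized ratios, so a shrinking of ratios by the high background of these arrays is not in the simulation. These shares thus do not show how many real changes the arrays could reveal. The count of 14 became 44, 3, 82 and 6 without TXOXTP replicates 1, 2, 3 and 4, and 423 with no background correction. Median centring gave 133 higher and 17 lower, and the call of Rn30016143 was lost without TXOXTP replicate 2 (3.36), with a trended and robust prior and in a fit of the TXOXTP arrays alone (limma adjusted p from 0.0037 to 0.51 over all alternatives). It was also lost without TXOXTP replicates 1 and 2 and TXOXTPGH replicate 4 together. This left only the TXOXTP replicate 3 value of the probe (4.43), so that loss tests nothing.

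TXOXTPGH against TXOX asks what both hormones together changed. They raised 877 probes and lowered 1021, with a median size of 0.60 on the log2 scale, and 164 of the raised and 41 of the lowered ones changed by 2-fold or more. Rn30016143 stood at 6.26 (SD 1.05, n = 4, limma adjusted p = 3.8e-06), Rn30008202 at 5.94 (SD 0.93, n = 4, limma adjusted p = 3.8e-06) and R000733_01 at -1.03 (SD 0.33, n = 4, limma adjusted p = 0.0024). Rn30012216, at -0.28 (SD 0.09, n = 4, limma adjusted p = 0.13), did not pass. It passed as a fall with median centring (-0.59), and its sign turned with the median of pixels as foreground (0.11; 0.05 with no background correction as well), while R000733_01 ranged from -1.36 to -0.46 over the alternatives. Of the probes called in INTACT, 290 of 1006 were also raised and 352 of 1040 also lowered, where independent lists would share 62.3 and 74.9 and the simulated groups, with almost no calls, 0. With different TXOX rats on the 2 sides, 25 to 166 higher and 2 to 180 lower probes were shared over the halvings. Independent lists would share a mean of 9.41 and 7.10, and up to 28.9 and 23.8 in single halvings, and the same limit holds. In all 3 of INTACT, TXOXGH and TXOXTPGH, 73 probes were higher and 66 lower. Of the 1898 probes called, 683 were above background in Cy5 on none of the TXOXTPGH arrays. The count became 905, 785 and 1153 without TXOXTPGH replicates 1, 2 and 3 and 1193 with no background correction, and median centring gave 535 higher and 1727 lower. It was 675 when the TXOXTPGH arrays were fitted alone, where the TXOXGH arrays alone gave 1485. The order of the counts of these groups thus depends on the arrays in the fit.

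**Figure D2:**
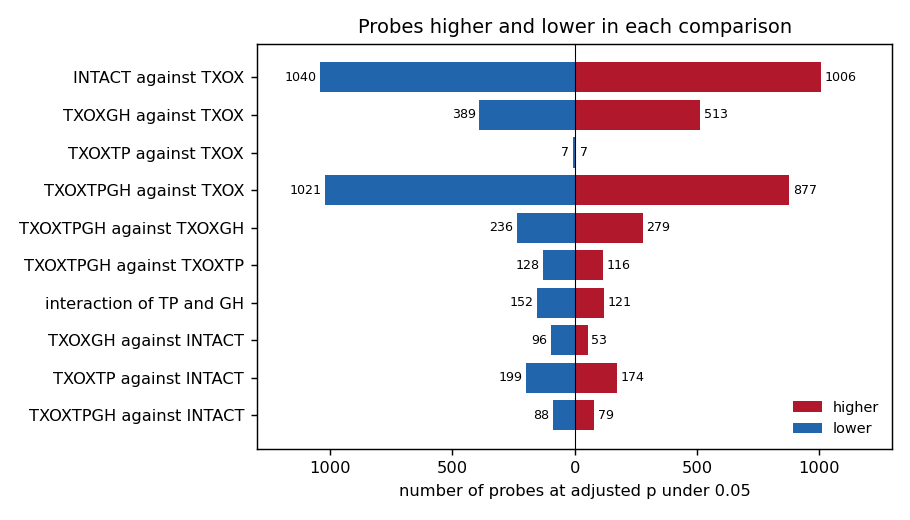
Number of probes higher (bars to the right) and lower (bars to the left) at a limma adjusted p under 0.05 in each of the 10 comparisons, of 14170 probes tested. INTACT against TXOX has 1006 higher and 1040 lower probes, and TXOXTP against TXOX 7 of each; median centring in place of loess gave other splits, such as 665 and 1306 for INTACT against TXOX.

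TXOXTPGH against TXOXGH asks what testosterone propionate added to growth hormone. With it, 279 probes were higher and 236 lower, with a median size of 0.92 on the log2 scale. Rn30012216 had a measured difference of 1.42 (SE 0.17, limma adjusted p = 0.00049), from -1.70 with growth hormone alone to -0.28 with both hormones. Its test RNA was above background on 2 of 4 TXOXGH and 1 of 4 TXOXTPGH arrays, and its TXOX signal on all 4 of each. Both ratios may therefore lie lower than measured, so neither the size nor the presence of the difference is settled. The other named probes did not pass, at 0.86 (SE 0.82, limma adjusted p = 0.60) for Rn30016143, 0.91 (SE 0.82, limma adjusted p = 0.58) for Rn30008202 and 0.41 (SE 0.28, limma adjusted p = 0.43) for R000733_01, though Rn30008202 did with no background correction and the median of pixels (3.05) and R000733_01 with the submitters' values (0.94). Of the 515 probes, 193 were above background in Cy5 on none of the TXOXTPGH arrays. Among the 487 probes above background in both channels on every array with a value, 79 were higher and 103 lower, adjusted over those probes, and these 182 became 80 without TXOXGH replicate 2 and 117 and 101 without TXOXTPGH replicates 2 and 3. The comparison crosses the batches, and no value within a batch can be had for it. The count of 515 became 254, 113 and 252 without TXOXGH replicates 1, 2 and 4, 259, 154, 316 and 892 without TXOXTPGH replicates 1, 2, 3 and 4, and 152 higher and 1048 lower with median centring.

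TXOXTPGH against TXOXTP asks what growth hormone added to testosterone propionate, within 1 batch as the Alien spots mark it. The arrays of the 2 groups still differed, with a median Cy3 background of 585 to 1143 on TXOXTP and 38 to 177 on TXOXTPGH arrays. An offset between these arrays cannot be told apart from an effect of growth hormone. In TXOXTPGH 116 probes were higher and 128 lower, with a median size of 1.02 on the log2 scale. Rn30008202 had a measured difference of 3.79 (SE 0.82, limma adjusted p = 0.027), but TXOX signal was above background on no TXOXTP array, so the TXOXTP ratio is a lower bound and the size of the difference is not known. Its call was lost without TXOXTP replicate 1 or 4 (3.21 and 3.15), without TXOXTPGH replicate 1, 2 or 3 (3.53, 3.57 and 3.83), with a trended and robust prior and in a fit of these arrays alone (limma adjusted p from 0.0072 to 0.12 over all alternatives). Rn30016143, with the same limit, differed by 2.04 (SE 0.89, limma adjusted p = 0.22), R000733_01 by -0.44 (SE 0.28, limma adjusted p = 0.41) and Rn30012216 by 0.04 (SE 0.17, limma adjusted p = 0.93), and these 3 did not pass. With the submitters' values, and with no background correction and the median of pixels, Rn30016143 passed (2.70 and 3.12). With median centring R000733_01 passed (-0.97) and Rn30012216 turned sign (-0.42), as R000733_01 did with the submitters' values (0.02) and Rn30012216 without TXOXTP replicate 3 (-0.07). Of the 244 probes, 92 were above background in Cy5 on none of the TXOXTPGH arrays. The count of 244 became 95, 77 and 73 without TXOXTP replicates 1, 2 and 4, and 45, 30, 107 and 668 without TXOXTPGH replicates 1, 2, 3 and 4. It was 22 when the arrays of these groups were fitted alone, and median centring gave 203 higher and 1558 lower.

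The interaction asks whether both hormones together changed a probe by another amount than the sum of their separate changes. It was called at 273 probes, 121 above and 152 below the sum. Rn30012216 had a measured value above the sum by 1.74 (SE 0.21, limma adjusted p = 0.0010). The limit of signal given for TXOXTPGH against TXOXGH holds here, so neither its size nor its presence is settled. Rn30016143 at -3.36 (SE 1.06, limma adjusted p = 0.095), Rn30008202 at -1.24 (SE 1.01, limma adjusted p = 0.52) and R000733_01 at 1.01 (SE 0.34, limma adjusted p = 0.11) did not pass, and the TXOXTP ratios of the first pair are lower bounds. Rn30016143 passed with median centring (-4.20) and without TXOXTP replicate 1 (-4.32). R000733_01 passed with the median of pixels (1.28), with no background correction (1.14), with both (1.33) and with the submitters' values (1.42), and Rn30008202 turned sign with the median of pixels (0.84) and with that and no background correction (1.48). Of the 273, 112 were also called in TXOXTPGH against TXOX, 177 in TXOXTPGH against TXOXGH, which crosses the batches, 106 in TXOXTPGH against TXOXTP, within a batch, and 61 in both of the latter. The term joins groups of both batches, so an offset of the batch of TXOXGH is not removed from it. Nor is an offset between the TXOXTP and TXOXTPGH arrays. Of the 273, 120 were above background in Cy5 on no TXOXTPGH array. In simulated data of this term with 14170 probes and 200 changed, 2 of 100 changes of 1.5-fold and 25 of 100 of 2-fold were recovered, again with changes added in full to normalized ratios. The count became 180 and 177 without INTACT replicates 1 and 4, 145, 64 and 81 without TXOXGH replicates 1, 2 and 4, 70 and 142 without TXOXTP replicates 2 and 4, and 106, 90 and 170 without TXOXTPGH replicates 1, 2 and 3. Median centring gave 132 above and 1359 below, and a fixed dye bias enters this term.

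The comparisons with INTACT ask what still differed from euthyroid rats with testes after each treatment, and a fixed dye bias cancels in them. After growth hormone 53 probes were higher and 96 lower than in INTACT, after testosterone propionate 174 and 199, and after both 79 and 88. Of the 149, 373 and 167 probes, 8, 163 and 88 were above background in Cy5 on no array of the treated group. Rn30012216 had measured values above INTACT in every treated group, by 1.14 (limma adjusted p = 0.0041) after growth hormone, 2.53 (limma adjusted p = 6.6e-08) after testosterone propionate and 2.57 (limma adjusted p = 5.0e-08) after both (SE 0.17 each). R000733_01 also had measured values above INTACT, by 1.41 (limma adjusted p = 0.020), 2.26 (limma adjusted p = 0.00013) and 1.82 (limma adjusted p = 0.0023), with SE 0.28 each. Test RNA at Rn30012216 was above background on 1 INTACT, 2 TXOXGH, 3 TXOXTP and 1 TXOXTPGH arrays. At R000733_01 these numbers were 1, 4, 3 and 2, so the sizes of these differences are not exact. Where test RNA was above background on only 1 or 2 arrays of a treated group, its ratio may lie lower than measured. The presence of the difference from INTACT is not settled there either. Both probes were chosen for their low INTACT values, which can enlarge the differences. The growth hormone call at R000733_01 was lost without INTACT replicate 2 or 3 (1.25 and 1.29) and without TXOXGH replicate 1, 2 or 4 (1.41, 1.28 and 1.29). Both growth hormone calls were lost with the median of pixels (0.96 for R000733_01 and 0.85 for Rn30012216), with that and no background correction (0.76 and 0.69), with the submitters' values (0.74 and 0.69) and with a trended and robust prior (1.41 and 1.14). Rn30008202 had a measured difference from INTACT of -3.88 after testosterone propionate (SE 0.82, limma adjusted p = 0.014), but its TXOXTP ratio is a lower bound, with TXOX signal above background on none of those arrays and on 1 INTACT array, so neither the size nor the presence of a gap is settled, and the call was lost with the median of pixels (-1.61), with that and no background correction (-1.58) and with the submitters' values (-1.06). Its other differences were -1.01 (limma adjusted p = 0.74) and -0.10 (limma adjusted p = 0.97), and those of Rn30016143 were -1.15, -2.33 (with the same limit) and -0.29, none of which passed. The -2.33 became -3.27 and passed with no background correction, with either foreground. The -0.10 turned sign under 8 alternatives (up to 2.43) and the -0.29 without TXOXTPGH replicate 4 (0.03), alone or with TXOXTP replicates 1 and 2.

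Counts of these 3 comparisons moved with single arrays and with the choice of probes. For growth hormone, 149 became 68, 87 and 77 without INTACT replicates 1, 2 and 3, and 59, 52, 82 and 60 without TXOXGH replicates 1, 2, 3 and 4. For testosterone propionate, 373 became 242 and 224 without INTACT replicates 2 and 3. For both, 167 became 59 and 110 without INTACT replicates 2 and 3, and 85, 83 and 278 without TXOXTPGH replicates 1, 2 and 4. Median centring gave 117 higher and 32 lower for growth hormone, 753 and 206 for testosterone propionate, and 60 and 123 for both. Among the 487 probes above background everywhere, 136 differed from INTACT after growth hormone (88 higher), 164 after testosterone propionate (116 higher) and 20 after both hormones (16 higher), adjusted over those probes. The 136 became 64 without INTACT replicate 3 and 67 and 39 without TXOXGH replicates 1 and 2, and the 164 became 108 without INTACT replicate 3 and 80 without TXOXTP replicate 2. The 20 became 10 and 12 without INTACT replicates 2 and 4, 13 without TXOXTP replicate 3, and 13, 11 and 38 without TXOXTPGH replicates 2, 3 and 4. Growth hormone alone shares the batch of INTACT, and the other treated groups do not.

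**Figure D3:**
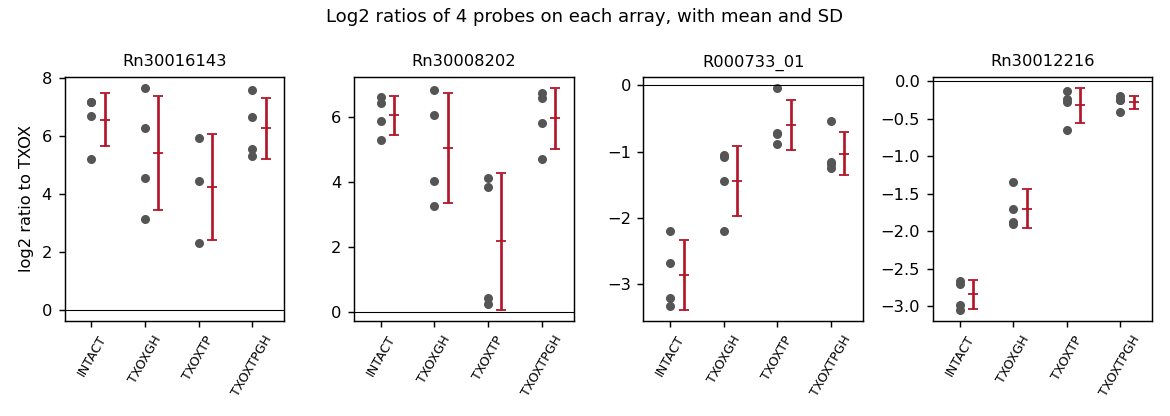
Log2 ratio to TXOX of the 4 named probes on each array (grey points), with the group mean and SD (red). Rn30012216 has means of -2.84 in INTACT, -1.70 in TXOXGH, -0.32 in TXOXTP and -0.28 in TXOXTPGH, the last turning to 0.11 with the median of pixels and standing at -0.59 with median centring; Rn30016143 has 3 values in TXOXTP.

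How far each treatment moved the liver towards the INTACT state was compared over all tested probes. Mean log2 ratios correlated with those of INTACT across probes with r of 0.63 for TXOXGH, 0.28 for TXOXTP and 0.57 for TXOXTPGH. Unchanged groups sharing the same TXOX rats would give 0.04 at the mean observed correlation of same-numbered arrays (0.0453), 0.31 at the highest (0.308) and 0.50 if test and TXOX rats varied equally. The covariances were 0.0789, 0.0279 and 0.0844, against simulated ones of 0.00117, 0.00804 and 0.0131. With different TXOX rats on the 2 sides, the slope on INTACT was 0.59 for TXOXGH (0.49 to 0.76 over 6 ways of halving the arrays), 0.20 for TXOXTP (0.10 to 0.34) and 0.66 for TXOXTPGH (0.47 to 0.93). In simulated data, a fixed dye bias of an assumed SD of 0.18 gave a slope of 0.20 to a TXOXTP group with a true slope of 0 and raised a true 0.4 to 0.52. These values follow from the assumed size, so the match with the measured 0.20 tells nothing. The covariance between different TXOXTP arrays, 0.0203 (0.0141 to 0.0308 without 1 array), was below the variance of such a bias. A smaller bias was not simulated and can enter the slope, so the value for TXOXTP is not shown to differ from no change. Of the 1006 probes higher in INTACT, 849, 709 and 827 lay above 0 in TXOXGH, TXOXTP and TXOXTPGH, and of the 1040 lower ones 877, 695 and 865 lay below 0, shares that the common TXOX rats raise without any effect.

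The probes with strong signal gave other slopes. Over the 487 probes above background everywhere, the slope was 0.29 for TXOXGH (0.17 to 0.43), 0.18 for TXOXTP (0.06 to 0.29) and 0.88 for TXOXTPGH (0.71 to 1.10). Over the 487 probes of highest mean intensity, chosen after these slopes were seen, it was 0.39 (0.33 to 0.47), 0.22 (0.16 to 0.33) and 0.87 (0.70 to 1.07). In both sets the ranges of TXOXGH and TXOXTPGH did not overlap, while over all tested probes they did. The mean squared log2 distance to INTACT, with noise removed, was 0.127 for TXOX, 0.0584 for TXOXGH, 0.0958 for TXOXTP and 0.0681 for TXOXTPGH over all tested probes, where the ranges over halvings of TXOXGH (0.055 to 0.0612) and TXOXTPGH (0.0521 to 0.0776) overlapped. Over the 487 probes above background everywhere it was 0.236, 0.189, 0.247 and 0.0785. A fixed dye bias stays in the distances of TXOX and cancels in those of the treated groups. A distance below that of TXOX therefore does not by itself show a move towards INTACT. Median log2 ratios over the 487 probes were -0.18 in INTACT, 0 in TXOXGH, 0.07 in TXOXTP and -0.14 in TXOXTPGH. Such shifts enter these distances. With TXOXTP as the baseline in place of TXOX, which removes a fixed dye bias, the slope over all tested probes was 0.49 for TXOXGH (0.42 to 0.60) and 0.60 for TXOXTPGH (0.46 to 0.90). Since TXOXTP then stands on both sides, its own reproducible ratios alone would give 0.21, and 0.35 with the least favourable array left out and halving. A batch offset is not removed from the value for TXOXGH there.

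**Figure D4:**
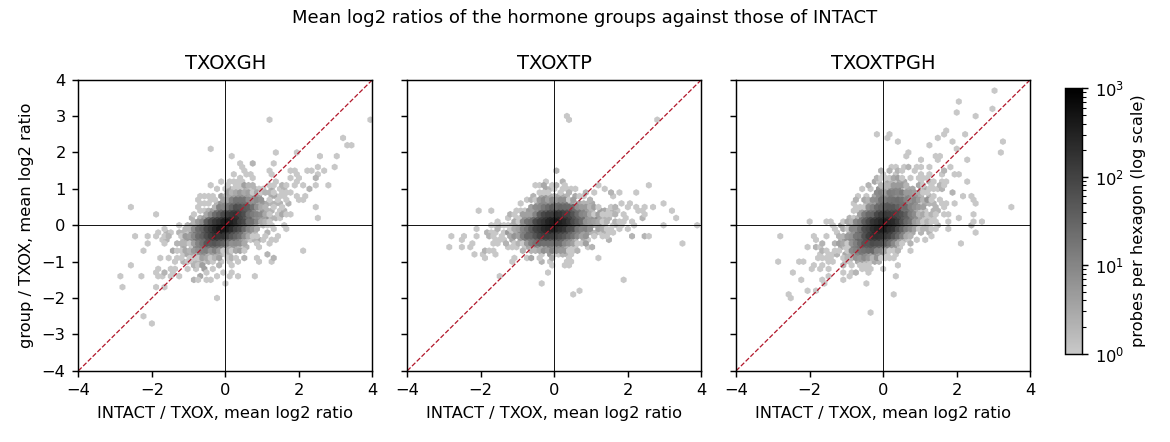
Mean log2 ratio to TXOX of each tested probe in TXOXGH, TXOXTP and TXOXTPGH (vertical axes) against that in INTACT (horizontal axes), with darker hexagons holding more probes and a dashed line of equal ratios. The correlations across probes are 0.63, 0.28 and 0.57; axes end at 4 on the log2 scale, which leaves out 9, 8 and 10 probes.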

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

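The tests of weak signal, of noisier TXOXTP arrays, of the array batch and of added testosterone propionate over the probes above background everywhere were chosen after the result was seen, as were the no-change values beside the slopes and the shuffles among arrays that share a TXOX rat; the tests of shared TXOX rats, of dye bias, of added testosterone propionate over all tested probes and of other splits were not. An array far from the others was sought in 43 tests, each of 1 measure or named probe within 1 group of 4 arrays, and 5 found one. Chance gives about 1 in 20 such tests, which reuse the same arrays and are not independent.

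INTACT replicate 2 had a mean correlation of 0.518 with its own group, against 0.557 to 0.565 for the others. The median Cy5 background of TXOXTP replicate 4 was 633, against 712 to 713 for the others. In TXOXTPGH replicate 4, 5.4% of probe spots were above background in Cy5, against 11.5% to 12.3%. The median Cy3 background of TXOXTPGH replicate 1 was 177, against 38 to 57. The log2 ratio of R000733_01 on TXOXTPGH replicate 4 was -0.54, against -1.255 to -1.158 on the other arrays of the group. The interaction test in limma called 273 probes, at which TXOXTPGH differed from the sum of the separate changes. A fixed dye bias and a batch offset stay in this term. Of the 273, 120 were above background in Cy5 on no TXOXTPGH array. Alien control spots, which no comparison used, were above background in Cy5 on at least 55.5% of spots in INTACT (empty spots up to 28.8%), 60.9% in TXOXGH (empty spots up to 37.6%) and 1.8% in TXOXTPGH (empty spots up to 0.7%).

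Few probes, 14, passed in TXOXTP against TXOX, on arrays with high background and low correlation between replicates. As the whole cause of the gap to INTACT, weak signal is argued against by the 487 probes above background everywhere, where TXOXTP had 0.116 of the calls of INTACT (0.198, 0.0238, 0.0664 and 0.0553 without TXOXTP replicates 1 to 4 and 0.207 without INTACT replicate 3), and noise by the covariance between different TXOXTP arrays there, 0.322 of that between INTACT arrays (0.237 to 0.484). For the gap to TXOXGH (14 against 902) weak signal, noise and a smaller effect cannot be told apart: over the 487 probes TXOXTP had 29 calls against 55, a ratio of 0.527 that was 0.111 without TXOXTP replicate 2, 0.296 and 0.232 without TXOXTP replicates 3 and 4, 0.907 without TXOXTP replicate 1 and 1 without TXOXGH replicate 2, and the covariance was 0.862 of that of TXOXGH (0.634 to 1.29) against 0.246 over all tested probes (0.15 to 0.404). A small effect of testosterone propionate alone stays open as a biological explanation, and so does a compression of ratios by the high background of these arrays, which was not tested. The count also rose to 423 with no background correction, so it may depend on that choice.

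Log2 ratios of the treated groups correlated with those of INTACT. Shared TXOX rats as the main cause are argued against for TXOXGH and TXOXTPGH, where arrays with different TXOX rats kept at least 0.76 and 0.726 of the covariance in each of 6 halvings. For TXOXTP the mean covariance of arrays with different TXOX rats was 0.0251, against 0.0279 between the means of all arrays. The lowest halving there was 0.436 (highest 1.59), so by the rule set beforehand the cause cannot be told apart. A fixed dye bias as the whole cause is argued against over all tested probes by slopes with TXOXTP subtracted (lowest halvings 0.42 for TXOXGH and 0.46 for TXOXTPGH), above the highest value of 0.35 that TXOXTP on both sides would give, though not for TXOXGH over the probes above background everywhere (0.27 against 0.30), nor for TXOXTP itself, which was not tested. The slope of TXOXTPGH with TXOXGH subtracted (lowest 0.55) decides nothing, and the bar of 0.1 set for it beforehand was too low, since TXOXGH on both sides alone would give 1.41. An offset between batches stays open for TXOXGH, and one between TXOXTP and TXOXTPGH, whose backgrounds differ, for TXOXTPGH; a partial return towards the INTACT state stays open as a hypothesis.

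TXOXTPGH differed from TXOXGH at 515 probes, across the batches that the Alien spots mark. Over all tested probes the batch and testosterone propionate cannot be told apart: TXOXTPGH against INTACT, which crosses the same batches, had 0.324 as many calls, but 0.789 with no background correction and the median of pixels and 0.492, 1.27 and 0.567 without TXOXGH replicates 1, 2 and 4, 0.539 without TXOXTPGH replicate 2, and 0.104 and 0.191 without INTACT replicates 2 and 3, and the slope towards INTACT (0.55 to 1.10) stays below the 1.41 that TXOXGH on both sides alone would give. The distances of TXOXTPGH and TXOXGH to INTACT were not set apart there: the squared distance was 0.0681 (0.0521 to 0.0776 over halvings) against 0.0584 (0.055 to 0.0612), r 0.57 against 0.63, the slope 0.66 against 0.59, and the calls 167 (59 to 278 without 1 array) against 149 (52 to 191). Over the 487 probes above background everywhere a batch offset unrelated to the INTACT difference, as the whole cause, is argued against by a ratio of calls of 0.11 (0.238 without TXOXGH replicate 2, 0.173 without TXOXTPGH replicate 4, and 0.051 and 0.0727 without INTACT replicates 2 and 4). The squared distance of TXOXTPGH there was 0.415 of that of TXOXGH (0.305 to 0.506 over halvings). Median log2 ratios over these probes were -0.18 in INTACT, 0 in TXOXGH, 0.07 in TXOXTP and -0.14 in TXOXTPGH. A shift of strong-signal probes on whole arrays in the INTACT direction would act on both the calls and the distances. Such a shift was not tested and stays open. That testosterone propionate brings rats on growth hormone closer to INTACT at probes with strong signal is a hypothesis found and tested on the same arrays.

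Only if the arrays are taken as unpaired is chance argued against as the source of the counts between test groups. There, 1 of 35 splits of the 8 arrays, the real one, gave as many probes in each, with no allowance for the number of comparisons. The real counts and the highest of the other splits were 515 and 0 for TXOXTPGH against TXOXGH, 244 and 10 for TXOXTPGH against TXOXTP, 149 and 15 for TXOXGH against INTACT, 373 and 1 for TXOXTP against INTACT, and 167 and 75 for TXOXTPGH against INTACT. Same-numbered arrays share a TXOX rat, and the splits that part them number 8, too few for a share under 0.05. With the pairing kept, chance is therefore not excluded for these counts. The highest others among the 8 were 0, 10, 1, 0 and 0. For the interaction, 2 of 100 shuffles of the residuals, the real arrangement included, gave as many as 273 probes, the highest being 497. Of the shuffles among arrays that share a TXOX rat, 2 of 100 did, the highest being 443. Both shares are under 0.05, but the shuffles swap residuals between groups of unequal spread (SD 0.284, 0.395 and 0.358 for TXOXGH, TXOXTP and TXOXTPGH). They also make no allowance for the 10 comparisons, so chance is not excluded for the interaction. Against TXOX, 8 sign patterns are too few for a share under 0.05: 1 gave as many in each, with real counts and highest others of 2046 and 1 for INTACT, 902 and 1 for TXOXGH, 14 and 2 for TXOXTP, and 1898 and 353 for TXOXTPGH.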

How the results depend on the processing

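Alternatives with array weights, a filter per group, no background correction together with the median of pixels, probes of the highest mean intensity and 3 arrays left out (TXOXTP replicates 1 and 2, TXOXTPGH replicate 4) were chosen after the result was seen. Of the counts of called probes, 94 stayed within 1.5 times the main count and 76 did not, and with 1 array left out 110 did and 50 did not. The 94 include the counts with Aquantile between arrays, which test nothing. The 110 include counts without an array outside the comparison, which enters only through the shared spread. Such an array moved a count only in the interaction (INTACT replicates 1 and 4). The 110 therefore do not show that the counts are stable. The cause of a moved count was not tested unless given here. The median of pixels moved no count. Nor did the replicate block, which changed no call of a named probe either and gave 2188, 950, 17 and 1939 against TXOX (INTACT, TXOXGH, TXOXTP, TXOXTPGH), 566 and 292 for TXOXTPGH against TXOXGH and TXOXTP, 338 for the interaction, and 164, 439 and 173 against INTACT (TXOXGH, TXOXTP, TXOXTPGH). Aquantile between arrays left every ratio as it was (largest difference 0), which tests nothing. With no background correction the counts were 3104 for INTACT, 423 for TXOXTP and 1193 for TXOXTPGH against TXOX, 162 for TXOXTPGH against TXOXTP, 614 for the interaction, 347, 679 and 268 against INTACT (TXOXGH, TXOXTP, TXOXTPGH), and r was 0.36 for TXOXTP on INTACT. With that and the median of pixels they were 594 for TXOXTP and 879 for TXOXTPGH against TXOX, 529 for the interaction, 583 and 291 for TXOXTP and TXOXTPGH against INTACT, and r was 0.36 for TXOXTP on INTACT. Print-tip loess gave 587 for TXOXGH and 31 for TXOXTP against TXOX, 434 for TXOXTPGH against TXOXTP, 249 for TXOXGH against INTACT, and r of 0.56 for TXOXGH on INTACT. Median centring gave 150 for TXOXTP against TXOX, 1200 and 1761 for TXOXTPGH against TXOXGH and TXOXTP, 1491 for the interaction, 959 for TXOXTP against INTACT, and r of 0.19 for TXOXTP on INTACT, and it moved group median log2 ratios by at most 0.05, as for INTACT (-0.06 against -0.01). With no filter on dim probes the counts were 8 for TXOXTP against TXOX, 295 and 85 for TXOXTPGH against TXOXGH and TXOXTP, 91 for the interaction, 87 and 109 for TXOXGH and TXOXTPGH against INTACT, and r was 0.49 for TXOXTPGH on INTACT. Over the probes above background in both channels on every array, fewer probes were tested (487), with 250, 55, 29 and 249 calls against TXOX in the order above, 182 for TXOXTPGH against TXOXGH, 138 for the interaction (72 without TXOXGH replicate 2 and 77 without TXOXTP replicate 2), 164 and 20 for TXOXTP and TXOXTPGH against INTACT, r of 0.41 and 0.77 and slopes of 0.29 and 0.88 for TXOXGH and TXOXTPGH on INTACT. Over the probes of the highest mean intensity r was 0.56, 0.35 and 0.80 for TXOXGH, TXOXTP and TXOXTPGH on INTACT, with slopes of 0.39 for TXOXGH and 0.87 for TXOXTPGH. Without not-found spots there were 1277 for INTACT, 501 for TXOXGH and 57 for TXOXTP against TXOX, 390 for TXOXTPGH against TXOXTP, r of 0.42 for TXOXTP and 0.70 for TXOXTPGH on INTACT, and a slope of 0.84 for TXOXTPGH. The filter per group gave 986, 360, 91 and 1219 against TXOX, 98 for TXOXTPGH against INTACT, r of 0.46 for TXOXTP and 0.76 for TXOXTPGH on INTACT, and a slope of 0.84 for TXOXTPGH. Fits of only the arrays compared, with fewer samples, gave 1485, 3 and 675 for TXOXGH, TXOXTP and TXOXTPGH against TXOX, 22 for TXOXTPGH against TXOXTP, and 183 and 73 for TXOXTP and TXOXTPGH against INTACT. A 1.5-fold minimum, which removes small changes, left 1009, 563 and 1014 for INTACT, TXOXGH and TXOXTPGH against TXOX. A variance prior with trend and robust estimation together gave 89 for TXOXGH against INTACT. The submitters' values, a chosen list, gave 1507, 781 and 973 for TXOXGH, TXOXTP and TXOXTPGH against TXOX, 107 and 102 for TXOXTPGH against TXOXGH and TXOXTP, 47 for the interaction, 58, 70 and 35 against INTACT, r of 0.88, 0.67 and 0.85 on INTACT, and slopes of 0.71 for TXOXGH and 0.34 for TXOXTP. Array weights gave 2223 for TXOXGH and 108 for TXOXTP against TXOX, 1036 for TXOXTPGH against TXOXGH, 523 for the interaction, and 452 and 586 for TXOXGH and TXOXTP against INTACT. Without the 3 arrays there were 1166 and 136 for TXOXTPGH against TXOXGH and TXOXTP, 70 for the interaction, and 248, 168 and 396 against INTACT. With 1 array left out the counts ranged from 913 to 2395 for INTACT, 358 to 1049 for TXOXGH, 3 to 82 for TXOXTP and 785 to 2356 for TXOXTPGH against TXOX, 113 to 892 and 30 to 668 for TXOXTPGH against TXOXGH and TXOXTP, 64 to 391 for the interaction, and 52 to 191, 224 to 399 and 59 to 278 against INTACT; the arrays that move them stand with each comparison. On INTACT, r ranged from 0.58 to 0.64 for TXOXGH, from 0.18 (without TXOXTP replicate 2) to 0.32 for TXOXTP and from 0.50 (without INTACT replicate 3) to 0.61 for TXOXTPGH, and slopes from 0.52 to 0.64, 0.13 to 0.25 and 0.59 to 0.78. For the named probes, 1201 values under alternatives kept their direction and side of the threshold, 27 no longer passed, 18 newly passed and 17 turned sign, and the losses and gains stand with each comparison. The sign turned for Rn30012216 in TXOXTPGH against TXOX with the median of pixels (0.11) and with that and no background correction (0.05). It turned for the same probe in TXOXTPGH against TXOXTP with median centring (-0.42) and without TXOXTP replicate 3 (-0.07, with 1 array left out up to 0.10), and there for R000733_01 with the submitters' values (0.02). For Rn30008202 in TXOXTPGH against INTACT it turned with no background correction (0.23), the median of pixels (2.23), both (2.43), array weights (0.07), the 3 arrays left out (0.32), and without INTACT replicates 2 and 4 and TXOXTPGH replicate 4 (0.09, 0.03 and 0.32, with 1 array left out down to -0.35). For Rn30016143 there it turned with the 3 arrays left out (0.03) and without TXOXTPGH replicate 4 (0.03, with 1 array left out down to -0.74). For Rn30008202 in the interaction it turned with the median of pixels (0.84) and with that and no background correction (1.48). Signal over background was a limit on the TXOXTP and TXOXTPGH arrays, with 5.4% to 21.6% of probe spots above background in Cy5. A scan day block and gene list alternatives were not run, the first because the file headers give no day and the others because the files pair no probe with a name.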

Other observations

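The slopes over the probes of the highest mean intensity and the no-change values were chosen after the result was seen. TXOXGH and TXOXTPGH shared 90 raised and 86 lowered probes against TXOX, where independent lists would share 31.8 and 28.0, but all comparisons against TXOX use the same 4 TXOX rats. Over the 487 probes above background everywhere, adjusted over those probes, 83 were higher and 167 lower in INTACT than in TXOX, 29 and 26 in TXOXGH, 19 and 10 in TXOXTP, and 95 and 154 in TXOXTPGH. The INTACT total of 250 became 150 without INTACT replicate 3, the TXOXGH total of 55 became 25 and 36 without TXOXGH replicates 2 and 4, and the TXOXTP total of 29 became 49, 6, 16 and 13 without TXOXTP replicates 1 to 4. Over these probes, and with a test group in place of TXOX as the baseline, the slope on INTACT was 0.27 for TXOXGH (0.20 to 0.33, TXOXTP subtracted), 0.88 for TXOXTPGH (0.76 to 1.09, TXOXTP subtracted) and 0.99 for TXOXTPGH (0.90 to 1.10, TXOXGH subtracted). The subtracted group on both sides would alone give 0.30, 0.30 and 0.45, so the value for TXOXGH does not pass its no-change value. Over the probes of the highest mean intensity these slopes were 0.26 (0.19 to 0.32), 0.82 (0.65 to 1.06) and 0.93 (0.81 to 1.08), with no-change values of 0.26, 0.26 and 0.63.

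TXOXTP replicate 4 had 7792 spots scored as bad, against 885 to 2938 on the other TXOXTP arrays and 45 to 114 on the INTACT and TXOXGH arrays. Of the called probes, 258 of 2046 in INTACT against TXOX and 46 of 902 in TXOXGH against TXOX were above background in Cy5 on no array of the group, shares below the 683 of 1898 in TXOXTPGH against TXOX and those of the comparisons with TXOXTP or TXOXTPGH given in the report. TXOXTP against TXOX went the other way, with 0 of 14. In Cy3 the counts above background on no array were 69 for INTACT, 40 for TXOXGH, 1 for TXOXTP and 196 for TXOXTPGH against TXOX. The share over all tested probes is not given here, so these shares cannot be read as a trait of the called probes. Among the submitters' listed probes tested here, 54.3% for INTACT, 44.8% for TXOXGH, 1.45% for TXOXTP and 51.4% for TXOXTPGH were called here with the same sign, with 0, 2, 0 and 5 probes called with the opposite one.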
